A study of Bos taurus with 68 samples.

How the data were processed

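Liver RNA from 5 cows (6934, 6983, 7079, 7186 and 7188) was hybridised to 2-colour cDNA microarrays on days -65, -30, -14, 1, 14, 28 and 49 relative to calving. Each sample was set against a reference standard RNA, and each cow and day was measured on a pair of arrays with the dyes exchanged. Cow 6983 had no day 49 sample, so the 68 arrays made up 34 cow-days. Per the labels, images were taken on a Scanarray 4000 scanner and quantified with GenePix 4.0. The deposited values are log2 ratios of the 2 dye channels at each spot. Background subtraction, spot flags and normalization are not given in the sources used here. No channel intensities were used, so neither the signal over background nor an intensity-dependent (loess) correction within an array was available, and the number of arrays limits the precision of every value.

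The deposited log2 ratios came as 2 tables from different array prints. The larger table held 60 arrays with 16416 rows, and the smaller table held 8 arrays with 16896 rows. The smaller table covered days -14 and 14 of cow 6934, day -14 of cow 7079 and day 14 of cow 7188. All tests were run within the larger table, which left 5 cows on days -65, -30, 1 and 28, 3 cows on days -14 and 14, and 4 cows on day 49. Between 14607 and 16288 rows were measured on an array of the larger table. Array medians lay between -0.95 and 0.64 in the larger table and between -0.45 and 0.075 in the smaller table, so each array was centred on its median.

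The labels name the dye of each sample but not which channel is the numerator. The sign of arrays with liver in Cy3 was turned, so that all ratios run as liver over reference if the deposited ratio is Cy5 over Cy3. The orientation labels were checked on the arrays, which says nothing about the numerator. The exchanged pair correlated below 0 across rows in 25 of the 30 cow-days of the larger table and in 4 of the 4 of the smaller table. Arrays of the same orientation never correlated below 0.08. The direction is only likely and rests on known tissue genes alone. After turning, 5 of 5 hepatocyte-enriched genes lay above the reference, and 8 of 11 genes of blood, muscle, brain and connective tissue lay below it. If the deposited ratio is Cy3 over Cy5, every sign turns, also of differences between days. The turned pair was averaged into 1 value per cow and day, with both orientations required.

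Each of the 5693 listed clones was spotted 2 times. Its spots correlated at 0.75 in the larger table and were averaged, and a clone is called a probe below. Clone annotation came from the platform's table, with symbols updated through gene identifiers to the ARS-UCD assembly's gene table for 5591 clones. Of the clones, 5598 named 1 gene, 95 named several and 0 named none. Clones with several genes were tested but never named. A further 5030 rows of the larger table had no clone or gene given here, so control spots among them cannot be told from other rows. They were left out and tested separately. No coordinates are given, because the array has no genome build. A probe was tested if it had a value in at least 3 cows on each day, which kept 5280 probes, 4966 of them measured in every cow-day.

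Fits used limma 3.58.1 in R 4.3.3. The model had fixed terms for day and cow over all 7 days, with empirical Bayes moderation and 19 residual degrees of freedom. The day effect was a moderated F test over the days, and 5 contrasts were tested with Benjamini-Hochberg adjusted p under 0.05, all 2-sided. P-values rest on the spread left after the terms for day and cow, pooled over all 7 days. This spread also holds array noise. Each comparison has at most 5 cows. The cow is a block because the same animals were sampled repeatedly. Deviations from the day means correlated on average at 0.13 between days of the same cow and at -0.03 between different cows on different days. The 2-colour ratios allowed no test of an absolute level.

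Gene lists were fixed before the data were examined. Of 29 lists, 2 served the ratio direction only and were not tested, and 3 had fewer than 5 genes on the array: secreted acute phase and coagulation proteins with 4, erythroid markers with 3 and mitochondrially encoded transcripts with 0. The other 24 were tested with camera at a preset inter-gene correlation of 0.01. Each gene was represented by its most completely measured probe, and adjustment ran over the lists. Because camera needs complete rows, the preset test used the moderated statistics of the fit (cameraPR). The alternatives with an estimated correlation and the rotation test fry used genes measured in every cow-day.

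Genes were named by a rule fixed before the data were examined. It took probes past the threshold that moved the same way in all cows but at most 1, up to 10 each way for day 1 against day -14 and for lactation against prepartum and up to 5 each way for the other contrasts. For the day effect it took, among probes past the threshold, up to 10 with the smallest p-values. It also took up to 4 members with the smallest p of each list, which are given here for the lists that passed in that comparison. Of 18 genes always to be given, 6 were on the array: CPT1A, ACADVL, PC, ACSL1, PDK4 and APOA1. Where a gene had several probes, the value is that of its representative probe, except in the figure of liver over reference, which shows clones.

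Scripts were tested on simulated data built from the residual spread of the 5280 probes, with 200 probes changed in each of 10 sets. For day 1 against day -14, 56.7% of 2-fold and 95.4% of 4-fold changes were recovered. For lactation against prepartum, 93.2% and 99.9% were recovered. Simulated probes were independent, unlike the real ones. Alternatives covered normalization, filters, dye orientation, the cow block, the variance model, array weights, both tables joined, each cow left out and the list tests. A further 7 alternatives were chosen after seeing the data: scaling on the mean profile or on the median absolute deviation, cyclic loess, centring by block of rows, single spots, rows without a clone, and leaving out the cow-days whose exchanged arrays did not oppose.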

Results

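Liver gene expression was followed in 5 cows from day -65 before calving to day 49 of lactation on 2-colour cDNA arrays. Values are log2 ratios of liver over a reference standard RNA, averaged over a pair of arrays with exchanged dyes, and 30 cow-days of the larger table entered the tests. This direction is only likely, and with the ratio the other way every lower below, between days too, reads higher. There were 5 cows on days -65, -30, 1 and 28, 3 on days -14 and 14, and 4 on day 49. The arrays hold no count of molecules, and their number limits the precision.

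Of 5 hepatocyte-enriched genes fixed beforehand, which also served to infer the direction of the ratio, transferrin (TF) lay at 3.78 ± 0.29 (SD, n = 5 cows) and ASGR2 at 2.46 ± 0.54, but ASS1 at 0.61 ± 0.33 and APOA1 at 0.06 ± 0.21. Among the named clones with the highest ratios were SERPINA3-3, a serine protease inhibitor of the acute phase, at 5.91 ± 0.66, and HAVCR1 at 5.86 ± 0.68. Of the deposited values of size 4.9 or more, 22.8% equalled, to 3 decimals, the log2 of a ratio of whole numbers up to 40. Very low intensities would give such values, so these ratios are taken as not exact. The share expected by coincidence is not given. Ceruloplasmin (CP), the copper carrier of plasma, lay at 4.95 ± 0.48 and catalase (CAT) at 4.84 ± 0.46. SLC10A1, the bile acid uptake transporter of hepatocytes, lay at 3.78 ± 0.38. Among the lowest ratios were vimentin (VIM) at -4.11 ± 0.28 (other probe -4.20), COL1A2 at -2.18 ± 0.45 (other probe -3.79), TIMP1 at -3.30 ± 0.59 and stathmin (STMN1) at -3.15 ± 0.55, while the matrix gene MGP lay at 1.35 ± 0.53. In all 5 cows, 52 clones were at least 4-fold above the reference and 31 at least 4-fold below it. These signs take the likely direction of the ratio, and each value is set against the reference only.

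**Figure D1:**
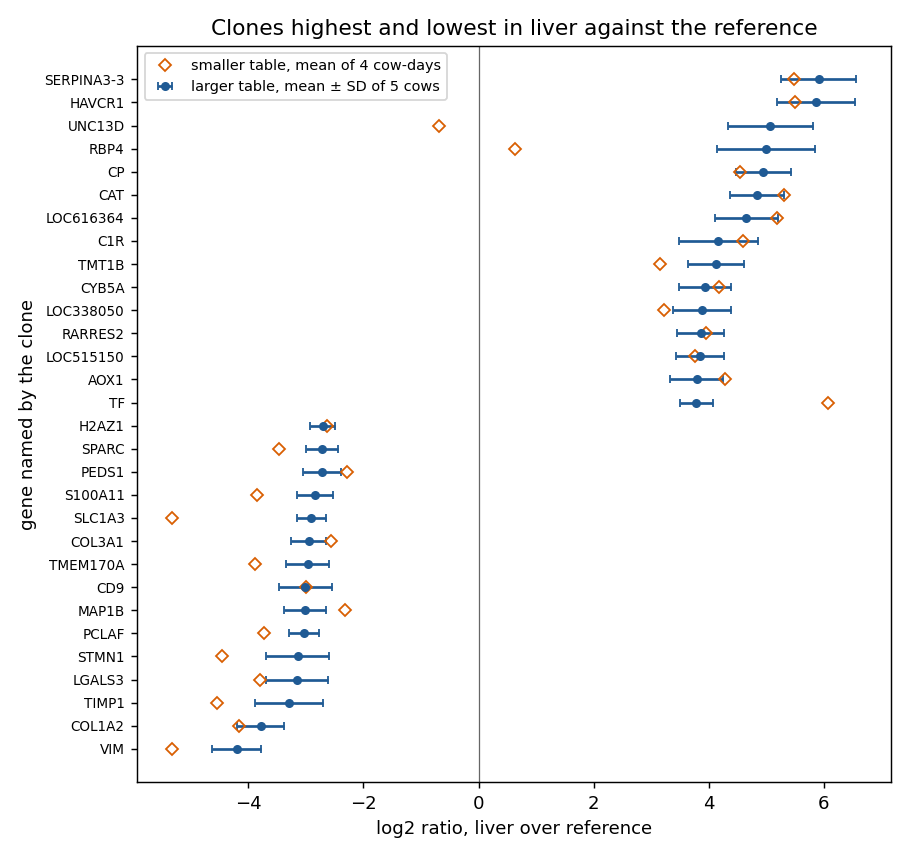
Log2 ratio of liver over reference for the 15 named clones with the highest and the 15 with the lowest mean, as mean ± SD of 5 cows in the larger table (filled points) and as the mean of 4 cow-days in the smaller table (open diamonds). SERPINA3-3 lies at 5.91 and the lower of the VIM clones at -4.20, while RBP4 and UNC13D differ between the tables.

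A single probe differed between the 7 days. It names LOC327709, a mu class glutathione S-transferase, an enzyme family that conjugates glutathione to electrophiles. Its log2 ratio was 3.75 ± 0.35 (SD, n = 5) on day -65, 4.05 ± 0.76 on day -30 and 3.37 ± 0.64 (n = 3) on day -14. In the likely direction of the ratio it was lowest on day 1, at 2.27 ± 0.36 (n = 5), and highest there if the ratio is turned, then 2.81 ± 0.47 (n = 3) on day 14, 3.55 ± 0.41 (n = 5) on day 28 and 2.70 ± 0.56 (n = 4) on day 49. The limma F test over days gave F = 12.5 with an adjusted p of 0.0146. Among 5280 probes, 276 had an unadjusted p under 0.05, where 264 would be so by chance. Each of the 5 contrasts below had fewer such probes than 264. None of the 5 contrasts passed for LOC327709. Its estimate was -1.07 ± 0.30 (SE) for day 1 against day -14 and -0.77 ± 0.17 for lactation against prepartum (adjusted p = 0.691), lower in 5 of 5 cows. The call was lost without the block for cow (adjusted p = 0.277) and with any 1 cow left out (adjusted p from 0.0827 to 0.490), and it was kept in 10 of 25 alternatives (adjusted p from 0.000187 to 0.490). Mu class genes are similar in sequence, and a cDNA probe can bind related transcripts.

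**Figure D2:**
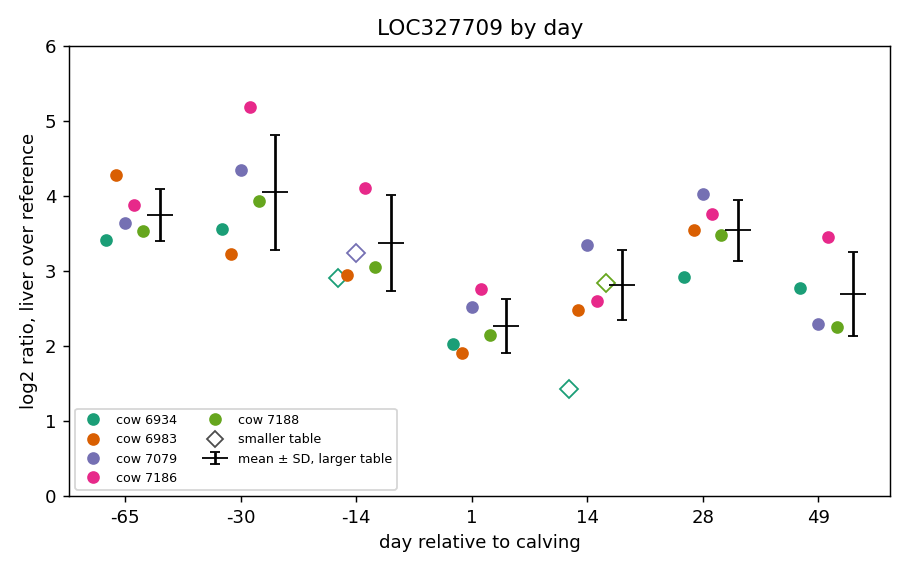
Log2 ratio of liver over reference of the LOC327709 probe against the day relative to calving, with a point per cow and the mean ± SD of the larger table beside them. Open diamonds are cow-days of the smaller table, which entered no test. In the likely direction of the ratio, day 1 has the lowest mean, 2.27, and day -30 the highest, 4.05.

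Late gestation was examined by comparing day -14 with day -65. No probe passed the test with limma (0 of 5280 past an adjusted p of 0.05, 158 at an unadjusted p under 0.05), and 0 of 24 gene lists were shifted, the smallest adjusted p being 0.214 for the stellate cell and extracellular matrix list. CPT1A, the carnitine transferase that admits fatty acids to mitochondria, had an estimate of -1.05 ± 0.36 (SE) with an adjusted p of 0.999, and its other probe gave -0.47. PDK4, the kinase that restrains pyruvate oxidation, was at -0.56 ± 0.47. Pyruvate carboxylase (PC), which feeds gluconeogenesis, was at 0.34 ± 0.26, ACADVL at 0.01 ± 0.27, ACSL1 at -0.03 ± 0.60 and APOA1 at -0.28 ± 0.23. The median probe had a 95% interval of ± 0.57 on the log2 scale, with 3 cows sampled on both days.

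Calving was examined by comparing day 1 with day -14. Complement genes were shifted lower as a list, with 9 of 10 members below 0 and a median of -0.50 (camera, adjusted p = 0.0200, but adjusted p = 0.794 with an estimated correlation). Of 30 genes fixed for this list, 10 were on the array: C1QA, C1QB, C1QC, C1R, C1S, C2, C4A, CFD, CFP and CD59. C3, C5 and C9 were not among them. CFP (properdin) had an estimate of -0.82 ± 0.37 (SE), C1QC -0.81 ± 0.48, C4A -0.69 ± 0.47 and CD59 -0.55 ± 0.36. Macrophage and Kupffer cell markers were shifted lower too, with 18 of 24 below 0 and a median of -0.21 (adjusted p = 0.0343, but adjusted p = 0.835 with an estimated correlation). LGMN, a lysosomal protease, was at -1.13 ± 0.31, VSIG4, the complement receptor of Kupffer cells, at -0.80 ± 0.34 and CD68 at -0.51 ± 0.29. The 2 lists share C1QA, C1QB and C1QC. Cytosolic ribosomal proteins were shifted lower with 36 of 45 members below 0 and a median of -0.15 (adjusted p = 0.0343, but adjusted p = 0.991 with an estimated correlation), which became 0.06 with array weights. RPL28 was at -0.58 ± 0.29, RPS3 at -0.42 ± 0.26, RPLP1 at -0.38 ± 0.21 and RPL38 at -0.33 ± 0.22.

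No list was shifted without cow 7186 or without cow 7188 (0 lists each), and macrophage markers were also no longer shifted without cow 6983. The complement and macrophage calls were lost too with both tables joined, which gives day -14 all 5 cows, with only arrays with liver in Cy3 and with array weights. Of single probes, 0 of 5280 passed with limma and 123 had an unadjusted p under 0.05. Adjusted over the list alone, 1 macrophage marker (LGMN), 0 complement genes and 0 ribosomal genes passed, and over all probes 0 of each. Among the metabolic genes always given, ACSL1, which activates long-chain fatty acids, was at 0.78 ± 0.60 (SE), PDK4 at 0.59 ± 0.47, ACADVL at 0.20 ± 0.27, CPT1A at 0.18 ± 0.36, PC at 0.10 ± 0.26 and APOA1 at 0.02 ± 0.23. The fatty acid oxidation and ketogenesis list had 9 of 17 members above 0 (adjusted p = 0.644), and the gluconeogenesis list 4 of 9 (adjusted p = 0.877), with a median below 0 and a mean above 0.

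The first 2 weeks of lactation were examined by comparing day 14 with day 1. Stellate cell, fibroblast and extracellular matrix genes were shifted higher, with 20 of 26 above 0 and a median of 0.33 (camera, adjusted p = 7.5e-05, but adjusted p = 0.601 with an estimated correlation). The median was -0.06 without the cow-days whose exchanged arrays did not oppose. That leaves only cow 7079 on day 14, assumed to vary like the others. Its day 1 is left out too, so no cow then has both days. COL3A1, a fibrillar collagen, had an estimate of 1.62 ± 0.43 (SE), SPARC 1.25 ± 0.43, COL4A2 1.21 ± 0.44 and decorin (DCN) 0.84 ± 0.40. Genes of endoplasmic reticulum folding and secretion were shifted lower, with 37 of 46 below 0 and a median of -0.14 (adjusted p = 0.000805, but adjusted p = 0.601 with an estimated correlation). When arrays were not centred its median was 0.04, but the median of all probes moved by 0.18 then and the call was kept. SSR3, a subunit of the translocon complex, was at -0.60 ± 0.23, the disulfide isomerase P4HB at -0.59 ± 0.26, CRELD1 at -0.31 ± 0.19 and calreticulin (CALR) at -0.28 ± 0.18. Fatty acid oxidation and ketogenesis genes were shifted lower with 14 of 17 below 0 and a median of -0.28 (adjusted p = 0.0489, but adjusted p = 0.695 with an estimated correlation), a median of 0.01 after scaling to 1 median absolute deviation and 0.28 without the cow-days named above, again with 1 cow on day 14. This call was lost in 19 of 30 alternatives, among them the cow block as a random effect, only the days of the contrast in the fit and both tables joined. ACSL1 was at -0.73 ± 0.60 and ECI1 at -0.44 ± 0.32, though each was higher on day 14 in 2 of the 3 cows sampled on both days, CPT2 at -0.41 ± 0.36 and ETFB at -0.32 ± 0.23.

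The matrix and folding lists were no longer shifted without cow 6983, and fatty acid oxidation was no longer shifted without cow 6934 or without cow 6983. The matrix call was lost with only arrays with liver in Cy3, and the folding call with only arrays with liver in Cy5. Scaling to 1 median absolute deviation ended both of these calls too. No probe passed with limma (0 of 5280, 144 at an unadjusted p under 0.05). Adjusted over the list alone, 1 matrix gene (COL3A1) passed, and 0 of the other lists' genes. CPT1A was at 0.37 ± 0.36 (SE) while its other probe gave -0.41, PC was at -0.10 ± 0.26, PDK4 at -0.09 ± 0.47, ACADVL at -0.29 ± 0.27 and APOA1 at -0.26 ± 0.23.

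Later lactation was examined by comparing day 49 with day 14, with 2 cows sampled on both days. Ribosomal protein genes were shifted lower, with 36 of 45 below 0 and a median of -0.20 (camera, adjusted p = 0.00388, but adjusted p = 0.875 with an estimated correlation). RPS2 had an estimate of -0.68 ± 0.39 (SE), RPS15A -0.47 ± 0.31, RPL32 -0.41 ± 0.27 and RACK1 -0.35 ± 0.20. Matrix genes were shifted lower, with 20 of 26 below 0 and a median of -0.30 (adjusted p = 0.00427, but adjusted p = 0.775 with an estimated correlation), which was 0.01 without cow 7186 and 0.01 without the cow-days whose exchanged arrays did not oppose, which leaves 1 cow on day 14 and 2 on day 49. MMP2, a collagenase, was at -1.01 ± 0.43, COL3A1 at -0.81 ± 0.46, DCN at -0.78 ± 0.42 and fibronectin (FN1) at -0.75 ± 0.42. Both calls were lost without cow 6983 or without cow 7186, and with only arrays with liver in Cy3. The matrix call was also lost without the block for cow and with both tables joined. No probe passed with limma (0 of 5280, 105 at an unadjusted p under 0.05), and adjusted over the list alone 0 genes of either list passed. PC was at -0.54 ± 0.28, ACADVL at -0.48 ± 0.29, ACSL1 at -0.41 ± 0.63, PDK4 at -0.09 ± 0.50, CPT1A at 0.06 ± 0.38 and APOA1 at 0.42 ± 0.25.

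Lactation as a whole (mean of days 14, 28 and 49) was compared with the prepartum state (mean of days -65, -30 and -14). Complement genes were shifted lower, with 9 of 10 members below 0 and a median of -0.61 (camera, adjusted p = 4.5e-09, but adjusted p = 0.326 with an estimated correlation). C1R had an estimate of -1.01 ± 0.36 (SE), C4A -0.94 ± 0.26, C1QC -0.74 ± 0.27 and C2 -0.64 ± 0.28, each lower in 4 of 5 cows. Macrophage and Kupffer cell markers were shifted lower, with 19 of 24 below 0 and a median of -0.17 (adjusted p = 0.000150, but adjusted p = 0.428 with an estimated correlation). TIMD4, a receptor for dying cells, was at -0.47 ± 0.19, CD14, the endotoxin co-receptor, at -0.45 ± 0.18 and VSIG4 at -0.41 ± 0.19. Interferon response and antigen presentation genes were shifted lower with 14 of 17 below 0 and a median of -0.12 (adjusted p = 0.0210, but adjusted p = 0.428 with an estimated correlation). CD74, the invariant chain, was at -0.53 ± 0.23, TAP1 at -0.47 ± 0.19, CXCL9 at -0.36 ± 0.28 and BOLA-DRB3 at -0.31 ± 0.20. Lymphocyte and neutrophil markers (6 of 16 above 0, adjusted p = 0.701), endothelial markers (4 of 11, adjusted p = 0.701) and bile duct markers (4 of 10, adjusted p = 0.701) did not pass.

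Of the metabolic lists, 2 were shifted lower. Fatty acid oxidation and ketogenesis had 12 of 17 members below 0 and a median of -0.24 (adjusted p = 0.00247, but adjusted p = 0.682 with an estimated correlation). HSD17B10, a mitochondrial dehydrogenase, was at -0.59 ± 0.21 (SE), ACSL5 at -0.53 ± 0.27 with its other probe at 0.24, HADH at -0.52 ± 0.28 and ETFB at -0.48 ± 0.13. Urea cycle and amino acid metabolism had 14 of 17 below 0 and a median of -0.12 (adjusted p = 0.0162, but adjusted p = 0.428 with an estimated correlation). AHCY, which hydrolyses S-adenosylhomocysteine, was at -0.71 ± 0.22, the urea cycle enzymes ASL at -0.38 ± 0.15 and ASS1 at -0.33 ± 0.15, and IVD at -0.28 ± 0.16 with its other probe at 0.06. Endoplasmic reticulum folding and secretion was also shifted lower, with 32 of 46 below 0 and a median of -0.07 (adjusted p = 0.0190, but adjusted p = 0.682 with an estimated correlation). PDIA4 was at -0.42 ± 0.15, LMAN2 at -0.35 ± 0.16, CRELD1 at -0.24 ± 0.11 and SSR2 at -0.17 ± 0.09. Ribosomal proteins were shifted lower too, with 30 of 45 below 0 and a median of -0.08 (adjusted p = 0.0204, but adjusted p = 0.824 with an estimated correlation). RPS3 was at -0.39 ± 0.15, RPL10 at -0.26 ± 0.15, RPL18 at -0.23 ± 0.11 and RPLP1 at -0.20 ± 0.12. When arrays were not centred, the medians of the ribosomal, folding, interferon and urea cycle lists were 0.07, 0.07, 0.03 and 0.03, but the median of all probes moved by 0.14 then and all 7 lists kept their call. The ribosomal median was 0.00436 with array weights, where its call was lost.

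Of the genes always given, PC was at -0.16 ± 0.15 (SE), ACADVL at -0.16 ± 0.15, ACSL1 at -0.14 ± 0.33, PDK4 at 0.14 ± 0.26, CPT1A at 0.12 ± 0.20 with its other probe at -0.30, and APOA1 at 0.00293 ± 0.13. Gluconeogenesis (4 of 9 above 0, adjusted p = 0.843), the growth hormone and insulin axis (6 of 16, adjusted p = 0.258), xenobiotic and antioxidant genes (12 of 28, adjusted p = 0.179), fatty acid and triglyceride synthesis (7 of 20, adjusted p = 0.634) and cholesterol synthesis (5 of 10, adjusted p = 0.715) did not pass. Nor did lipoprotein export and bile acids (3 of 5, adjusted p = 0.634), glycolysis and glycogen (8 of 20, adjusted p = 0.363), the tricarboxylic acid cycle and oxidative phosphorylation (26 of 54, adjusted p = 0.715), heat shock (11 of 18, adjusted p = 0.715), proteasome (12 of 26, adjusted p = 0.828), translation factors (14 of 27, adjusted p = 0.701), cell cycle (10 of 18, adjusted p = 0.378), matrix genes (18 of 26, adjusted p = 0.258) and the adipose and muscle markers (7 of 7, adjusted p = 0.258). The median and the mean differed in sign for gluconeogenesis, cholesterol synthesis, lipoprotein export, the proteasome and the tricarboxylic acid cycle list. The xenobiotic list names mu class transferases such as GSTM1. LOC327709, the probe with a day effect, was matched to no list gene by symbol and did not enter that test.

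In this comparison 7 of 24 lists passed, all lower in the likely direction of the ratio (all higher if it is turned), and 0 of 24 passed with an estimated correlation. Without cow 7188, 3 lists passed. Calls ended without cow 6934 (ribosomal), 6983 (folding, interferon), 7079 (ribosomal, interferon), 7186 (ribosomal, interferon, urea cycle) and 7188 (ribosomal, folding, fatty acid oxidation, urea cycle), while the complement and macrophage lists passed without any 1 cow. Both were lost without the cow-days whose exchanged arrays did not oppose (1 cow left on day 14), with medians of -0.14 (adjusted p = 0.160) and -0.06 (adjusted p = 0.318), and the macrophage list also after scaling on the mean profile, with -0.11 (adjusted p = 0.185). Adjusted over the list alone, 3 complement genes, 1 fatty acid oxidation gene and 0 genes of the other 5 lists passed. Of single probes, 0 of 5280 passed with limma and 205 had an unadjusted p under 0.05, where 264 would be so by chance. The median probe had a 95% interval of ± 0.32 on the log2 scale. The slope of each cow-day on the mean liver to reference profile, a measure of how far the ratios were spread out, averaged 0.95 in lactation and 1.04 before calving. It was lower in lactation in 4 of 5 cows (exact sign-flip test, 2-sided p = 0.125, the smallest possible being 0.0625).

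**Figure D3:**
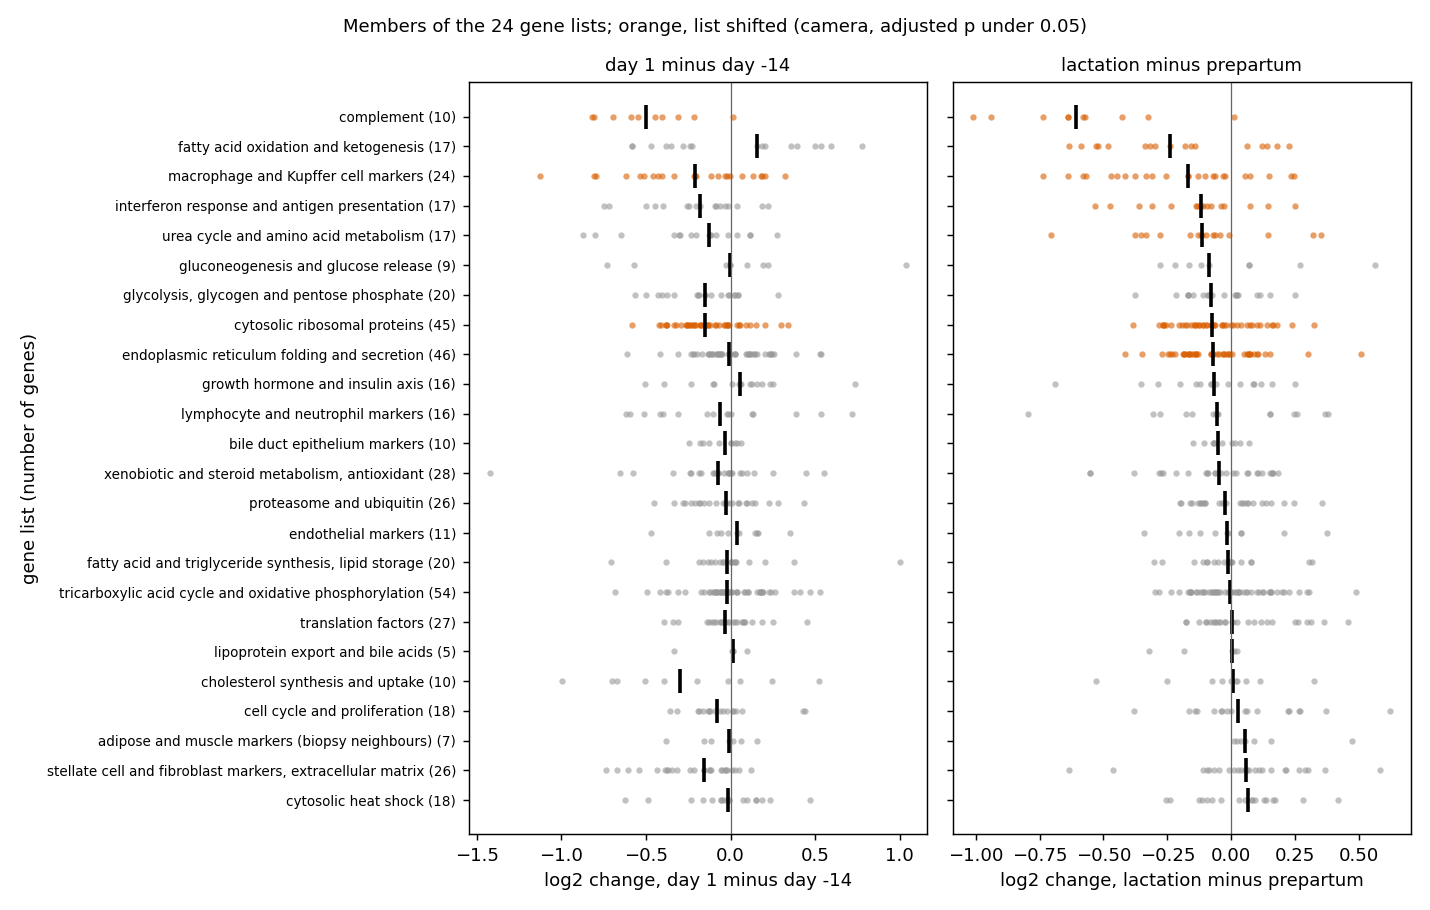
Log2 change of each member (points) and the median (bars) of the 24 gene lists, for day 1 minus day -14 and for lactation minus prepartum, with orange for lists shifted at an adjusted p under 0.05 with the preset correlation, of which 0 passed with an estimated one. The complement list has the lowest median in both, -0.50 and -0.61.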

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

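The test of macrophage content and the scaling of each cow-day on the mean profile were chosen only after the result was seen, and so was the use of the mean over cows and its standard error to read the 2 complement values.

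In 2 of 51 groups of 4 to 10 samples a cow lay far from the others, where chance gives 2.55. The difference between lactation and prepartum of RPS3 was -0.0563 in cow 6983 and -0.38 to -0.50 in the others. That of IVD was -0.92 in cow 7188 and -0.29 to -0.06 in the others. No explanation was tested for either.

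The complement list was lower in lactation than before calving, with a median of -0.61, lower in 4 of 5 cows. A loss of macrophages, which make C1Q, would leave the other complement genes near 0 only if macrophages make little of them, which was not tested. The median of these genes was -0.57. Their mean over cows, -0.49 with a standard error of 0.21, did not clear the bound of -0.3. For both reasons a loss of macrophages cannot be told apart. Nor can compression of all ratios, as from a weaker hybridisation. After scaling each cow-day on the mean profile the list's median was -0.32 and its mean over cows -0.24 with a standard error of 0.11, which spans the same bound. It passed then with the preset correlation (adjusted p = 9.2e-07), but before scaling it had adjusted p = 0.326 with an estimated correlation, which was not run on scaled values. Of the 6 other lists, 2 still passed after scaling, so compression may account for the calls of the rest. A lost call alone does not show how far a list's median shrank. Stage of lactation stays open and cannot be parted from the date of hybridisation, which the labels do not give.

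With array weights, 884 probes had a day effect, against 1 without. When days were shuffled within cows and weights estimated again, 2 of 100 orders, the real one included, gave as many, with 1108 the highest of the others. Estimating weights from the same data thus seldom gave as many by itself. Yet 75 of the other orders gave at least 1 probe. A weight over 3 was given to 5 of 30 cow-days, from 4 cows and each on a different day. Day 14 of cow 7186 (weight 3.92) and day 49 of cow 6934 (weight 3.75) were among them, and their exchanged arrays did not oppose. Whether the count rests on the cow-days of high weight was not tested. No biological explanation was tested.

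LOC327709 had a day effect, with lower values in lactation than before calving in 5 of 5 cows, though that contrast did not pass (limma, adjusted p = 0.691). Not every lactation day was lower, since the mean was 3.55 (n = 5) on day 28 and 3.37 (n = 3) on day -14. A single cow or a single dye orientation would bring the difference near 0. The values nearest 0 were -0.61 with 1 cow left out and -0.71 with 1 orientation. But the probe was picked for its day effect in these same values, with cow as a block. The cows' differences ran from -0.48 to -1.12, so leaving out 1 cow could hardly bring the mean above the bound of -0.38. Neither value is thus independent evidence against these causes. Both are of the difference between lactation and prepartum, which leaves out day 1. The day-effect call was lost with any 1 cow left out (limma, adjusted p from 0.0827 to 0.490) and with liver in Cy3 alone (adjusted p = 0.202) or Cy5 alone (adjusted p = 0.414). Ratio compression cannot be told apart, since the difference after scaling was -0.43, close to the bound of -0.38. That bound was set once the day effect was known. The standard error used to read it, 0.17, is that of the unscaled difference and spans the bound. The call also ended with that scaling (adjusted p = 0.440), as the difference shrank from -0.77. In cow 6934 of the smaller table, which entered no test, day 14 minus day -14 was -1.48, and 99 of 5580 clones were as low. Binding of related mu class transcripts was not tested, and the stage around calving stays open.

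Other assignments of the days within cows, or of the samples of the days compared, gave counts as large often enough that chance is not excluded for the day effect without array weights or for the gene lists of the 2 comparisons so tested. For the day effect, 5 of 100 orders gave 1 probe or more, the highest other being 1. For the 5 contrasts the real count was 0 probes, which every split equals, so the splits say nothing about chance there: 56 splits for day -14 against day -65 (highest other 1), 56 for day 1 against day -14 (highest 0), 56 for day 14 against day 1 (highest 5), 35 for day 49 against day 14 (highest 1) and 100 orders for lactation against prepartum (highest 13). At an unadjusted p under 0.05, another order gave up to 1048 probes for lactation where the real order gave 205, which may come from a structure of the samples other than the day or from probes that vary together. For gene lists at calving, 22 of 56 splits gave 3 or more (highest other 6), and 3 of the 8 splits that part as many pairs did (highest 5). For lists in lactation, 10 of 100 orders gave 7 or more (highest other 12). At least 1 list passed in 71 of the other orders for lactation and in 45 of the other splits for calving, with a median of 2 lists in each. Lists thus often passed with the preset correlation when days were exchanged, so its small adjusted p-values are not to be taken at their size.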

How the results depend on the processing

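Scaling on the mean profile or the median absolute deviation, cyclic loess, centring by block of rows, single spots, rows without a clone and leaving out cow-days with non-opposing exchanges were chosen only after the result was seen. Of 2424 alternative values of named genes, 2296 differed from the main estimate by less than the SD of the change over cows, and 88 turned sign. Some alternatives alter only the test, so the estimate stays the same there. No named gene had passed a contrast, so none could be reversed after a call. Of 457 list values, 315 kept their call and 142 lost it. Probes with a day effect numbered 0 with arrays not centred, quantile normalization, only arrays with liver in Cy5, no replicate block, no moderation across rows, division by the slope on the mean profile, scaling to 1 median absolute deviation, cyclic loess and without the cow-days whose swaps did not oppose, 2 with arrays as units and with each spot on its own, 884 with arrayWeights, and 0 to 0 without each cow. Only arrays with liver in Cy3 gave 1 probe for day -14 against day -65 and 1 for day 1 against day -14. With arrayWeights the 5 contrasts gave 5, 6, 7, 1 and 14 probes in the order of the report. LOC327709 was among the 14 for lactation against prepartum (limma, adjusted p = 0.0334). Without the cow-days whose swaps did not oppose, which leaves 1 cow on day 14, assumed to vary like the others, day 14 against day 1 gave 2 and day 49 against day 14 gave 4. Gene lists shifted on day 1 against day -14 were 0 with arrayWeights, estimated correlation, fry and cyclic loess, 1 with liver in Cy5, median absolute deviation, each spot and without non-opposing swaps (the last 2 kept 0 of the 3 lists), and 0 (without cow 7186 or 7188) to 4 without each cow. Lists shifted in lactation against prepartum were 0 with estimated correlation and fry, 2 with liver in Cy5 and median absolute deviation, 3 with the slope, cyclic loess and without non-opposing swaps, 4 with both tables joined, and 3 (without cow 7188) to 7 without each cow. The 7 without cow 7186 held 4 of the lists of the report and 3 others: adipose and muscle markers and matrix genes, both higher, and xenobiotic genes, lower. Leaving out a cow leaves fewer samples. Otherwise the cause was not tested. Signal over background was not analysed here.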

Other observations

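No test of this part was chosen after the result was seen, apart from the comparison between the tables and the test of rows without a clone.

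In the main fit, without array weights, more probes differed between cows than between days. With limma, 832 of 5280 probes differed between the 5 cows, against 1 between days, and 1781 had an unadjusted p under 0.05 between cows. Among 2158 pairs of rows with no clone given here, 0 differed between days with limma and 106 had an unadjusted p under 0.05.

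Most clones far from the reference in the larger table had the same sign in the smaller. Of 52 clones at least 4-fold above the reference in every cow, 50 had the same sign in the smaller table, as did 28 of 31 at least 4-fold below. Yet 5 of the 52 and 4 of the 31 lay within 1 of 0 there on the log2 scale or had the opposite sign. Over the clones in both tables, the mean ratios correlated at 0.69. UNC13D lay at 5.07 in the larger table and -0.68 in the smaller, SPINT1 at 3.73 and 0.58, and HTR6 at -2.58 and 1.35. In cow 6934 of the smaller table, day 14 minus day -14 had a median of -0.40 over macrophage markers (16 of 24 lower), -0.18 over ribosomal proteins and -0.02 over complement genes (6 of 10 lower). It was -0.12 over interferon genes, 0.10 over fatty acid oxidation, 0.10 over folding and 0.26 over urea cycle genes, against 0.06 over all clones.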
